A study of Mus musculus with 6 samples.

How the data were processed

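The series holds RNA-seq of mouse liver, 3 libraries labelled Sox9f/f (replicates 5, 6 and 8) and 3 labelled Sox9HKO (replicates 9, 10 and 12), all from mice on the same diet for 6 weeks per the labels. Messenger RNA was separated from total RNA before library construction per the labels' protocols, and whether the libraries kept strand is not given in the sources used here. Samples were grouped by the genotype label alone. No sex, date or batch label was used, and the groups shared no replicate numbers.

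The deposited table gives raw gene counts per the file headers, in whole numbers, for 34745 genes with Ensembl identifiers and coordinates. The same table gives FPKM values, deposited by the authors per the file headers. The FPKM of a gene equalled its count divided by a fixed gene length and by the library total, with the ratio constant to within 0.00934% over 13046 genes. HISAT2 2.0.4 and StringTie 1.3.0 and the builds mm10 and GRCm38.p4 are named per the submitters' processing notes, without their roles. The counting tool and annotation release are not given in the sources used here. Coordinates are printed as the table gives them. GENCODE M21 on GRCm38 supplied gene types, GC content and transcript length. It matched 34344 identifiers (98.8%), of which 27763 had the same coordinates, and 99.7% of tested genes had GC and length.

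Counts were tested with edgeR 4.0.16 in R 4.3.3, with filterByExpr, TMM scaling and the robust quasi-likelihood test, without covariates. The filter kept 14137 genes, which held at least 99.9% of counts in every library, and left out 20608. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors were derived from the fold change and its test statistic, and CPM values used TMM-scaled library sizes. The biological coefficient of variation was 0.216. Depth lay between 22826962 and 27286864 counts per library. No pair of libraries agreed within sampling noise, since the chi-square per degree of freedom between libraries was 34.3 or more. Library-size scaling alone would shift the median log2 fold change of all genes by 0.11 relative to TMM.

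Gene lists, the test and the rule for named genes were chosen before the data were examined. Lists of at least 5 tested genes were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, adjusted over 28 lists. Beside it stood camera with an estimated correlation, camera on ranks, and fry, which tests whether the genes of a list move one way on balance without comparing them with other genes. With an estimated correlation 0 of the 28 lists passed. Members were also tested adjusted over the list alone. The rule named Sox9, the 10 genes of largest change per direction among those called or, where fewer than 5 passed, the 5 of smallest p per direction with non-overlapping groups and a mean of at least 1 CPM. It further named up to 4 called members of each list or else the 2 of smallest p, and Prkaa1 and Prkaa2. No gene was called, so all named genes are given as values. Predicted gene models and pseudogenes were left out of the naming by smallest p. One gene of the hepatocyte list, Tf, was not analysed here.

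Alternatives were DESeq2 1.42.0, limma voom with sample quality weights, RLE, upper-quartile and library-size scaling, no filter (20074 genes), a stricter filter of 1 CPM in 3 libraries, a 2-fold threshold, limma on log2(FPKM + 0.5), a non-robust fit, and each library left out in turn. Alternatives added after the data were seen were a threshold of 0.1 and removal of each library's trend on transcript length and GC, fitted by splines with 4 degrees of freedom on each. DESeq2 gave no adjusted p for 558 genes, which were left as missing. Families of genes defined by their symbols, and further tests of explanations, were also chosen after results were seen.

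The scripts were tested on counts simulated from these libraries, with 200 of 14137 genes changed. edgeR recovered 0% of genes changed 1.5-fold, 8% at 2-fold, 70% at 4-fold and 80% at 8-fold, with 2 of 81 calls false. DESeq2 recovered 6%, 28%, 84% and 86% at those sizes, with 54 of 156 calls false. Camera with a preset correlation called a list shifted by 0.7 and 0 of 27 unshifted lists. The simulated genes varied independently of each other, so this cannot show how often camera calls unshifted lists of correlated genes. Figures were drawn with matplotlib 3.10.9.

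Genes that overlap another gene or have near-identical copies, such as Acot1 and Acot3, the Cyp2c genes, Hba-a2 and Cyp2b13, are uncertain, since the counting may have split or shared their reads. Whole-gene counts cannot show which exons were read, and strandedness of the counting was not stated.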

Results

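Liver RNA was sequenced from mice that had been fed an MCD diet for 6 weeks. Such a diet lacks methionine and choline and is used to bring on steatohepatitis, an inflamed fatty liver. There were 3 libraries labelled Sox9f/f, a floxed Sox9 genotype that served as the control, and 3 labelled Sox9HKO, a name read here as a loss of Sox9. Sox9 is a transcription factor of bile duct cells and of developing and injured liver. The table held 34745 genes, and total gene counts per library lay between 22826962 and 27286864. Replicates 5, 6 and 8 formed the Sox9f/f group, and replicates 9, 10 and 12 the Sox9HKO group. The p-values of single genes below measure the spread between these samples. Those of camera compare the genes of a list with other genes. With a preset correlation they do not take the correlation between genes from these samples.

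The targeted gene was examined first, in every library. Sox9 went against its label as read here, a loss of Sox9 in the tissue as a whole. The genotype label does not spell out in which cells Sox9 was to be lost. Liver RNA mixes cell types, so these counts do not show in which cells Sox9 changed. A loss limited to some cells need not lower the count of the whole liver. The libraries labelled Sox9f/f held 127, 138 and 143 Sox9 counts, and those labelled Sox9HKO held 411, 491 and 626. In CPM, the counts scaled to a common library size, this was 5.64 ± 0.282 (SD, n = 3) against 18.7 ± 3.74 (SD, n = 3), a log2 fold change of 1.73 ± 0.18 (SE), or 3.32-fold. All 3 libraries labelled Sox9HKO lay above all 3 labelled Sox9f/f. The edgeR adjusted p was 0.0830, above the threshold of 0.05, and that of DESeq2 was 7.88e-12. Over all alternatives the adjusted p of edgeR, DESeq2 and limma ranged from 7.88e-12 to 0.353, and the log2 fold change from 1.51 to 1.86. Sox9 (ENSMUSG00000000567) lies on chromosome 11 from 112782224 to 112787760 on the plus strand (GRCm38). Counts are summed over the whole gene, so they do not show whether the exons to be deleted were present. Every direction below is therefore one between the libraries labelled Sox9HKO and those labelled Sox9f/f, not one tied to a measured loss of Sox9.

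The first comparison asked which genes differed between the labelled genotypes. Besides Sox9, the genes with the smallest p that were higher in the libraries labelled Sox9HKO were Osbpl3, Zeb2, Cd24a and Lrat. Those lower were Banp, Lrtm1, Znhit2, Usp36 and Bhlha15. None of these 10 genes passed the threshold over all genes in edgeR, so their values are given without a call. Osbpl3, an oxysterol-binding protein family member, had 23.2 ± 3.57 CPM against 56.9 ± 7.01 (log2 fold change 1.29 ± 0.15). Zeb2, a zinc finger transcription factor also used by stellate cells and macrophages, had 9.31 ± 0.979 against 22.6 ± 2.85 (1.28 ± 0.15). Cd24a, a surface protein of ductular cells, stood at 1.21 ± 0.17. Lrat, which esterifies retinol in stellate cells, stood at 0.85 ± 0.13. Banp, a nuclear DNA-binding protein, had 11.5 ± 1.10 CPM against 3.54 ± 0.329 (-1.69 ± 0.17). Lrtm1, a leucine-rich repeat membrane protein, had 10.9 ± 3.01 against 2.57 ± 0.422 (-2.08 ± 0.25). Bhlha15, also called Mist1 and a transcription factor of secretory cells, had 34.7 ± 8.84 against 5.27 ± 2.98 (-2.72 ± 0.39). Znhit2 stood at -0.80 ± 0.11 and Usp36, a nucleolar deubiquitinase, at -0.92 ± 0.13.

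**Figure D1:**
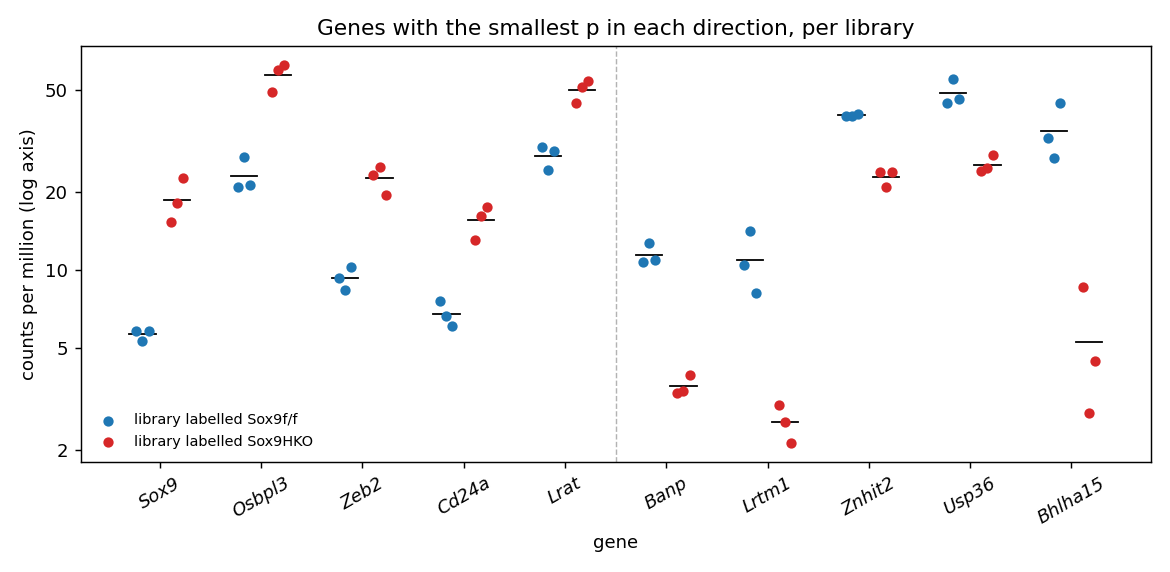
CPM (log axis) of 10 genes in each of the 6 libraries, points for libraries and bars for group means. Blue points are libraries labelled Sox9f/f and red points those labelled Sox9HKO. The 5 genes left of the dashed line were higher and the 5 right of it lower in the libraries labelled Sox9HKO, with Sox9 at 15.3 to 22.7 CPM there and 5.31 to 5.80 in the others.

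Osbpl3 (ENSMUSG00000029822) lies on chromosome 6 from 50293330 to 50456201. Zeb2 (ENSMUSG00000026872) lies on chromosome 2 from 44983632 to 45117395 and overlaps its antisense gene Zeb2os, so reads of the pair cannot be told apart where counting ignores strand. Banp (ENSMUSG00000025316) lies on chromosome 8 from 121949750 to 122029258. Lrtm1 (ENSMUSG00000045776) lies on chromosome 14 from 29018208 to 29033642, inside Cacna2d3.

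Of 14137 genes tested, edgeR called 0 higher and 0 lower at an adjusted p of 0.05. At an unadjusted p under 0.05 there were 2800 genes, 1377 higher and 1423 lower in the libraries labelled Sox9HKO, where chance alone gives 707. DESeq2 called 326 genes higher and 279 lower, and limma voom called 0. The groups did not overlap for 3752 genes, or 26.5%, where chance gives 10%. At an adjusted p under 0.1, a threshold added after the data were seen, edgeR gave Sox9, Osbpl3, Zeb2, Banp and Lrtm1. On simulated data of the same size edgeR recovered 70% of genes changed 4-fold and 8% of those changed 2-fold, with 2 false among 81 calls. In the same simulation 54 of the 156 calls of DESeq2 were false. Recovery and the share of false calls depend on how many genes change, and the simulation changed only a small part of them. How many genes truly differ here is not known, so these shares cannot be carried over to the calls in the real data.

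The series title names the AMPK pathway, so its genes were examined as a list. AMPK is a kinase that responds to low cellular energy. The catalytic subunits Prkaa1 and Prkaa2 had log2 fold changes of 0.06 ± 0.12 and 0.15 ± 0.11. Prkaa1 stood at 16.5 ± 0.361 CPM in the libraries labelled Sox9f/f and 17.2 ± 0.909 in those labelled Sox9HKO. Prkaa2 averaged 59.5 and 66.2 CPM. Both signs turned, to -0.11 each, once the trend on gene length and GC content was removed. The lowest p in the list belonged to the regulatory subunits Prkag1 (-0.31 ± 0.11) and Prkab1 (-0.24 ± 0.13). None of the 10 AMPK list genes tested passed in edgeR, over all genes or adjusted over the list alone, and DESeq2 called 0. At an unadjusted p under 0.05 there was 1. The list median was 0.08 and its mean -0.00, which differ in sign, and the camera adjusted p was 0.991. RNA levels do not measure phosphorylation or activity of the kinase.

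Matrix and ductular genes had positive medians in the libraries labelled Sox9HKO, whose Sox9 level goes against that label as read here. The matrix mean lay above all libraries labelled Sox9f/f in 3 of 3. The ductular mean did so by a near tie, since Sox9HKO replicate 9 stood at 2.139 and Sox9f/f replicate 6 at 2.132 (log2 CPM). Among 28 lists chosen before the data were examined, camera with a preset correlation called 11, of which 7 were higher and 4 lower. With an estimated correlation it called 0 of the 28 (lowest adjusted p = 0.401). The 27 matrix and stellate cell genes had a median log2 fold change of 0.70, and 26 were positive. In edgeR 0 of them passed over all genes and 15 passed adjusted over the list alone, with 16 at an unadjusted p under 0.05, while DESeq2 called 14. Lrat and Thbs2, a matricellular thrombospondin, led the list, Thbs2 at 5.51 ± 0.156 CPM against 9.62 ± 0.495 (0.80 ± 0.15). Collagen chain Col1a1, singled out after its values were seen, stood at 1.41 ± 0.31. The camera adjusted p of this list was 2.71e-08. It was 0.473 with an estimated correlation, the highest over its alternatives, whose lowest was 3.51e-10.

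All 13 ductular markers tested were positive, with a median of 0.78. Cd24a, Spp1 and Epcam passed in edgeR adjusted over the list alone, and 0 passed over all genes. At an unadjusted p under 0.05 there were 5, and DESeq2 called 3. Spp1, or osteopontin, had 46.7 ± 7.32 CPM against 128 ± 41.7 (1.45 ± 0.24), and Epcam, named after its values were seen, stood at 1.28 ± 0.23. For this ductular list the camera adjusted p was 2.48e-05, and adjusted p = 0.473 with an estimated correlation. Its alternatives ranged from 1.71e-07 to 0.473.

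Of 12 neutrophil markers on the list 7 were tested, and the filter left out the others. The 7 tested were all positive with a median of 0.72, and 1 passed in edgeR adjusted over the list alone. In that list 3 genes were under an unadjusted p of 0.05, and DESeq2 called 0. The gene that passed, Retnlg, was near the floor at 0.0609 ± 0.105 CPM against 0.736 ± 0.276, and Csf3r, the receptor of a neutrophil growth factor, stood at 0.83 ± 0.33. Retnlg stood at 0 CPM in Sox9f/f replicates 6 and 8, so only the libraries labelled Sox9HKO carried it past the filter. Its sign and its pass were thus favoured in advance. The neutrophil camera adjusted p was 0.00133, and adjusted p = 0.473 with an estimated correlation (2.25e-04 to 0.473 over alternatives). All 19 macrophage markers were positive with a median of 0.48, yet 0 passed in edgeR adjusted over the list alone, 1 was under an unadjusted p of 0.05, and DESeq2 called 0. The macrophage mean lay above all libraries labelled Sox9f/f in 2 of the 3 labelled Sox9HKO, not in replicate 12. Cd9 stood at 0.39 ± 0.13 and Adgre1, the F4/80 antigen, at 0.49 ± 0.22. The macrophage camera adjusted p was 0.00426, and adjusted p = 0.679 with an estimated correlation. Without Sox9HKO replicate 10 the macrophage call was lost at adjusted p = 0.137 (1.01e-04 to 0.679 over alternatives). The 14 T, NK and B cell markers had a median of 0.51, with Cd8a at 1.36 ± 0.52 and Cd79a at 1.07 ± 0.60, both under 2 CPM. The lymphocyte mean lay above all libraries labelled Sox9f/f in 2 of the 3 labelled Sox9HKO. In edgeR 0 of these lymphocyte genes passed adjusted over the list alone, 1 was under an unadjusted p of 0.05, and DESeq2 called 0. Their camera adjusted p was 0.0301, and adjusted p = 0.679 with an estimated correlation. The lymphocyte call was lost without Sox9f/f replicate 6 (0.418), Sox9f/f replicate 8 (0.0539) or Sox9HKO replicate 9 (0.130), over a range of 5.55e-04 to 0.679.

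The 21 cell cycle genes had a median of 0.50, and 18 were positive. Their mean lay above all libraries labelled Sox9f/f in 2 of the 3 labelled Sox9HKO, not in replicate 12. Mki67, a marker of cycling cells, had 2.01 ± 0.414 CPM against 7.44 ± 2.60 (1.89 ± 0.31), and Ccna2, a cyclin that overlaps Exosc9, had 1.48 ± 0.27. In edgeR 3 cell cycle genes passed adjusted over the list alone and 0 over all genes, and DESeq2 called 3. At an unadjusted p under 0.05, 7 were higher and 1 lower. Camera gave these genes an adjusted p of 0.00321, and adjusted p = 0.679 with an estimated correlation. Without Sox9HKO replicate 10 it was 0.0603, within a range of 7.12e-06 to 0.679.

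**Figure D2:**
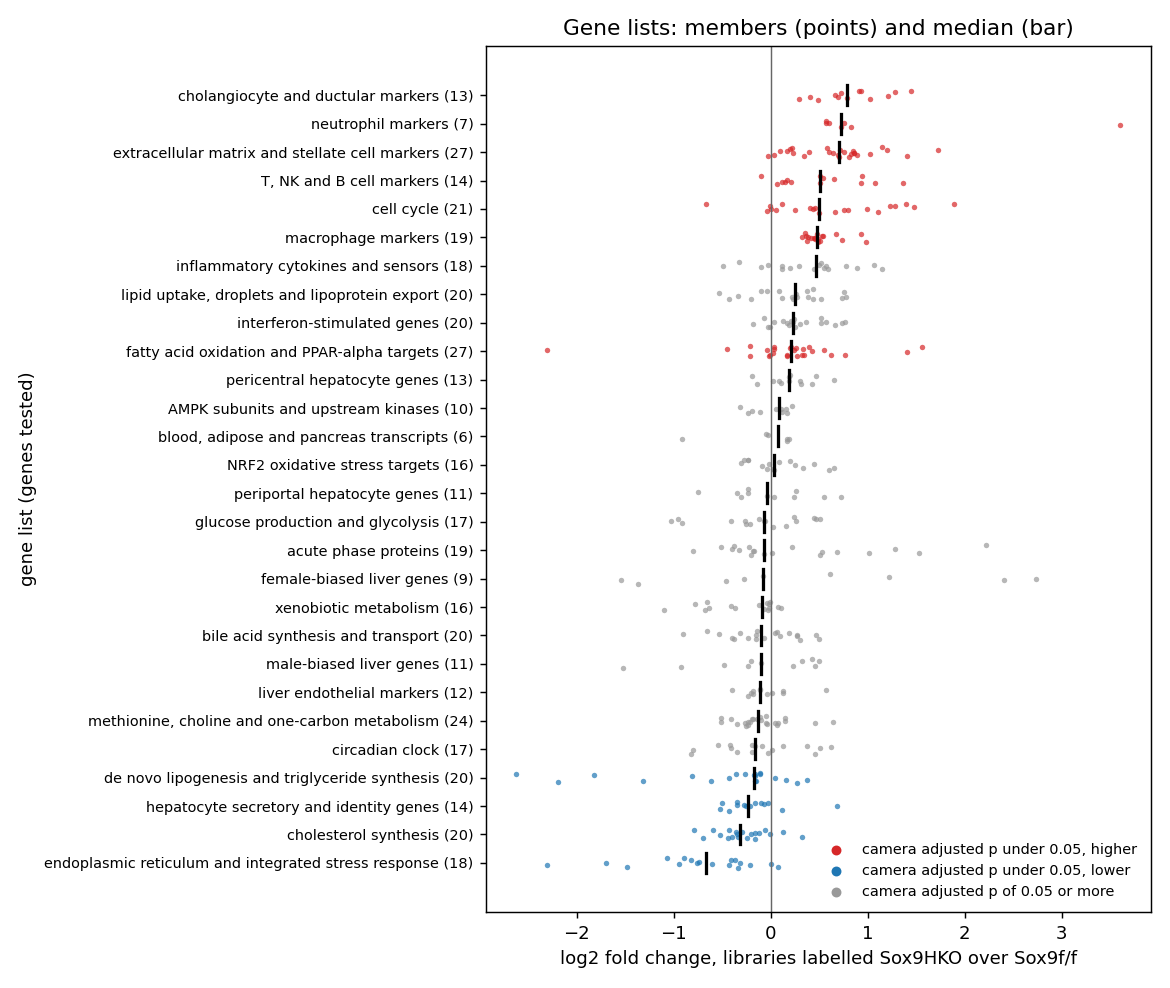
Log2 fold changes of the libraries labelled Sox9HKO over those labelled Sox9f/f for the genes of 28 lists, with points for genes, black bars for list medians and the number tested in brackets. Red and blue lists were past the camera threshold of 0.05 with a preset correlation, higher and lower, and grey lists were not; with an estimated correlation 0 lists passed. Medians ran from -0.67 for the stress response to 0.78 for ductular markers.

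Stress response and lipogenic genes had negative medians in the libraries labelled Sox9HKO, again a direction by label, and the mean of each list lay below all libraries labelled Sox9f/f in 3 of 3. Of 18 genes of the endoplasmic reticulum and integrated stress response, 16 were negative, and the median was -0.67. Ddit3, the stress-induced factor CHOP, had 31.2 ± 7.74 CPM against 9.60 ± 3.02 (-1.70 ± 0.27) and overlaps Mars. Hspa5, the chaperone BiP, had 850 ± 224 against 406 ± 107 (-1.07 ± 0.25). In edgeR 7 of the stress genes passed adjusted over the list alone and 0 over all genes, with 11 at an unadjusted p under 0.05, and DESeq2 called 3. In camera the stress list had an adjusted p of 3.03e-05, and adjusted p = 0.401 with an estimated correlation (2.63e-06 to 0.401 over alternatives).

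The 20 genes of lipogenesis and triglyceride synthesis had a median of -0.17 and a mean of -0.53, and 16 were negative. Fasn, the fatty acid synthase, had 715 ± 326 CPM against 202 ± 59.2 (-1.82 ± 0.39). Lpin1, a phosphatidate phosphatase, had 382 ± 135 against 153 ± 33.7 (-1.32 ± 0.26). In edgeR 5 lipogenic genes passed adjusted over the list alone and 0 over all genes, with 6 at an unadjusted p under 0.05, and DESeq2 called 3. Among the 5 was Pnpla3, near the floor at 0.578 CPM against 0.123, which only the libraries labelled Sox9f/f could carry past the filter. Camera gave an adjusted p of 0.00731, and adjusted p = 0.401 with an estimated correlation (0.00194 to 0.401 over alternatives). The 20 cholesterol synthesis genes had a median of -0.32, and 18 were negative, with a mean below all libraries labelled Sox9f/f in 2 of the 3 labelled Sox9HKO. Fdps stood at -0.69 ± 0.18 and Fdft1 at -0.40 ± 0.12, both sterol pathway enzymes with an overlapping gene, and 0 passed in edgeR adjusted over the list alone. At an unadjusted p under 0.05 there were 7 cholesterol genes, and DESeq2 called 1. In camera the adjusted p was 0.00384, and adjusted p = 0.679 with an estimated correlation. The cholesterol call was lost without Sox9f/f replicate 8, at 0.0592 (3.01e-04 to 0.679 over alternatives).

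The 27 genes of fatty acid oxidation and PPAR-alpha targets had a median of 0.20, with 20 positive and 7 negative. The pair that passed in edgeR adjusted over the list alone were Pdk4, a kinase that restrains pyruvate dehydrogenase, and Acot1, a thioesterase with close paralogs, rather than enzymes of the oxidation spiral. Pdk4 had 50.2 ± 23.6 CPM against 148 ± 22.7 (1.56 ± 0.32), and Acot1 stood at 1.41 ± 0.31. In edgeR 0 passed over all genes, 6 higher and 1 lower were under an unadjusted p of 0.05, and DESeq2 called 3. The camera adjusted p was 0.0136, and adjusted p = 0.679 with an estimated correlation. The call was lost without Sox9f/f replicate 5 (0.0656), Sox9f/f replicate 8 (0.130), Sox9HKO replicate 10 (0.0611) or Sox9HKO replicate 12 (0.0781), over a range of 4.74e-04 to 0.679.

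The 14 hepatocyte secretory and identity genes had a median of -0.23, and 12 were negative. F2, or prothrombin, stood at -0.43 ± 0.12, while Tdo2, a tryptophan-degrading enzyme, went the other way at 0.68 ± 0.19. In edgeR 0 hepatocyte genes passed adjusted over the list alone, 1 higher and 3 lower were under an unadjusted p of 0.05, and DESeq2 called 1 higher and 1 lower. Albumin transcripts took 7.18% to 7.49% of counts in the libraries labelled Sox9f/f and 6.05% to 6.55% in those labelled Sox9HKO. The camera adjusted p was 0.0300, and adjusted p = 0.473 with an estimated correlation. The hepatocyte call was lost without Sox9f/f replicate 5 (0.0732), Sox9f/f replicate 6 (0.0604) or Sox9HKO replicate 9 (0.161), and once the length and GC trend was removed (0.15), over a range of 0.00494 to 0.473.

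The other 17 lists did not pass in camera. Choline and methionine genes, relevant to the diet, had a median of -0.13, with Chdh at 0.46 ± 0.11 and Pemt, which makes phosphatidylcholine, at -0.41 ± 0.11. The camera adjusted p of that list was 0.104, and that of fry 0.0243 (0.0243 to 0.473 over alternatives). Glucose genes had a median of -0.07, with the fructose and glycolytic kinases Khk at -1.03 ± 0.25 and Pklr at -0.92 ± 0.24, both past the threshold adjusted over the list alone. Lipid uptake and droplet genes had a median of 0.25, with Lpl at 0.78 ± 0.17 and Cidec at 0.73 ± 0.19, likewise past it over the list alone. Inflammatory cytokines had a median of 0.47, with Il1b at 1.15 ± 0.34 and Ccl3 at 1.07 ± 0.41. Interferon-stimulated genes had a median of 0.23, with Oasl2 at 0.66 ± 0.30 and Ifit2 at 0.77 ± 0.37. Acute phase genes had a median of -0.07 but a mean of 0.25, with Apcs at -0.81 ± 0.14, past the threshold over the list alone, and Lcn2 at 1.01 ± 0.31.

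Endothelial markers had a median of -0.11, with Gpr182 at -0.40 ± 0.14 and Lyve1 at 0.57 ± 0.31. NRF2 targets had a median of 0.03, with Gclc at 0.60 ± 0.14, past the threshold over the list alone, and Ugdh at 0.34 ± 0.17. Bile acid genes had a median of -0.10, with Slc51b at -0.91 ± 0.40 and Hsd3b7 at -0.65 ± 0.29. The bile acid mean relative to the Sox9f/f average was 0.13 and 0.09 in Sox9HKO replicates 9 and 10 and -0.69 in replicate 12. Without replicate 12 the camera direction of that list turned to higher (adjusted p = 0.474). Pericentral genes had a median of 0.19, with Znrf3 at 0.65 ± 0.22 and Slc1a2 at 0.47 ± 0.26. Periportal genes had a median of -0.04, with Etnppl at 0.72 ± 0.27 and Cyp2f2 at -0.75 ± 0.30. Xenobiotic genes had a median of -0.09, with Cyp2c37 at -0.68 ± 0.25 and its paralog Cyp2c29 at -0.63 ± 0.27, which can share reads. Clock genes had a median of -0.16, with Bhlhe40 at -0.55 ± 0.19 and Ciart at -0.80 ± 0.28. Male-biased genes had a median of -0.10, with Nudt7 at -0.48 ± 0.11, past the threshold over the list alone, and Hsd3b5 at -1.52 ± 0.59. Female-biased genes had a median of -0.08 and a mean of 0.36, with Acot3 at 1.22 ± 0.32 and Cyp2b13 at -1.55 ± 0.42, both past it over the list alone. The Y-linked genes Ddx3y (17.1 to 30.3 CPM) and Eif2s3y (20.1 to 27.8 CPM) were expressed in every library of both labels, so each held male tissue. Blood, adipose and pancreas transcripts had a median of 0.07 and a mean of -0.08, with Cela2a at -0.92 ± 0.71 and Hba-a2 at 0.17 ± 0.47. For that list the camera direction followed the mean. The camera adjusted p of these 16 lists other than the choline list ran from 0.104 to 0.991.

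Libraries within a label were not alike. Sox9f/f replicate 5 correlated slightly more with Sox9HKO replicate 9 (Pearson r = 0.9804) than with Sox9f/f replicates 6 (0.9781) and 8 (0.9782). On the first principal component it stood at -8.27, replicates 6 and 8 at -33.2 and -35.7, and the libraries labelled Sox9HKO at 19.7 to 33.7. Sox9HKO replicate 12 stood apart on the second principal component, at -48.9 against -4.50 to 20.6 for the others. Without it, edgeR called 1 gene higher and 1 lower (Cd63-ps and Thrsp), and without Sox9f/f replicate 5 it called Erbb3, Tsku and Zfp395. Without Sox9HKO replicate 12 camera called 15 lists, at the preset correlation like all list calls in this paragraph. The interferon list was then among them at an adjusted p of 3.98e-07, over a range of 3.98e-07 to 0.859. With an estimated correlation and all 6 libraries its adjusted p was 0.813. The inflammatory, pericentral, NRF2 and periportal lists were also called without Sox9HKO replicate 12. The inflammatory list was called without Sox9f/f replicate 5, the male-biased list without Sox9HKO replicate 9 or 10, and the xenobiotic and endothelial lists without Sox9HKO replicate 10. The male-biased, xenobiotic and endothelial lists were called lower, with means relative to the Sox9f/f average of -1.51, -0.89 and -0.39 in Sox9HKO replicate 12. In Sox9HKO replicates 9 and 10 these means were 0.18 and 0.09, -0.23 and 0.02, and -0.05 and 0.18. Without Sox9HKO replicate 12 the camera direction of the male-biased (adjusted p = 0.885) and endothelial (0.734) lists turned to higher. DESeq2 called 158 genes without Sox9f/f replicate 8, 222 without Sox9f/f replicate 6, 185 without Sox9HKO replicate 10 and 984 without Sox9HKO replicate 12, against 605 with all 6 libraries. Genes at an unadjusted p under 0.05 in edgeR numbered 1810 without Sox9f/f replicate 8 and 1792 without Sox9HKO replicate 10.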

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

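The threshold of 0.1 and the length and GC removal were chosen after the data were seen, and the other alternatives before. DESeq2 called 326 genes higher and 279 lower in the libraries labelled Sox9HKO and edgeR without a filter called 4 and 6, where edgeR with the filter called 0 and 0 (2800 at an unadjusted p under 0.05); the causes were not tested. The 10 genes called without a filter had all passed it and included Sox9, Banp, Osbpl3, Lrtm1 and Zeb2. At an adjusted p under 0.1 edgeR gave 3 and 2. Other scalings, the stricter filter, voom, FPKM values, the non-robust fit and the length and GC removal gave 0 and 0. A 2-fold threshold on top of 0 calls could give only 0 and says nothing of stability. Leaving out each library gave 0 to 2 genes higher and 0 to 1 lower. Sox9 kept its direction in every alternative run and passed 0.05 with DESeq2 (1.74) and without a filter (1.73), and the 0.1 threshold in edgeR, with adjusted p between 7.88e-12 and 0.353. Camera called 11 lists, 11 on ranks, 10 with the trend removed, 8 to 15 with a library left out, 3 with fry and 0 with an estimated correlation. Those of fry were lipogenesis (fry adjusted p = 0.0243), the stress response (0.0445) and the choline list (0.0243). The matrix (0.102), ductular (0.120) and neutrophil (0.102) lists did not pass in fry. Under each single left-out library the matrix, ductular, stress, neutrophil and lipogenesis lists kept their calls. For 65 named genes other than Sox9, 1026 alternative values gave 980 with the same direction and side, 41 newly past the threshold (35 of them with DESeq2) and 5 of the other sign. The last were Hba-a2 with voom (-0.33), Hba-a2 without Sox9f/f replicate 5 or Sox9HKO replicate 12 (-0.24 to 0.58 over the 6 left-out libraries, 2 of them of the other sign), and Prkaa1 (-0.11) and Prkaa2 (-0.11) with the trend removed; the cause was not tested. Pseudocount and median-centring alternatives did not apply, since counts were the main unit. No paired analysis was possible because the groups share no replicate numbers. At this depth and spread, 2-fold changes were mostly not recovered in a simulation that changed only a small part of the genes.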

Other observations

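The gene families, the single mitochondrial gene, both ductular tests, the label question, the hepatocyte share test, the clock test and the separate length and GC tests of the higher lists and of the hepatocyte list were chosen only after results were seen. Of 15 families defined by gene symbol, camera with a preset correlation put 12 past 0.05, 7 once the trend on length and GC was removed, and 0 with an estimated correlation (lowest adjusted p = 0.191). Kinesins, motor proteins that include mitotic ones, had a median log2 fold change of 0.43 over 36 genes in the libraries labelled Sox9HKO, and 0.43 with the trend removed. The 25 collagens, 6 of which the matrix list also holds, had a median of 0.69, and DESeq2 called 9 of them higher. The 11 laminins, basement membrane proteins, were all positive with a median of 0.47. Of 77 mitochondrial ribosomal proteins 73 were negative, with a median of -0.28, and -0.19 with the trend removed, while DESeq2 called 5 of them lower and the adjusted p was 0.285 with an estimated correlation. Cytosolic ribosomal proteins had -0.19, which became -0.04 with the trend removed and an adjusted p = 0.105. Library-size scaling would move these medians by 0.11 and turn none of the signs given before trend removal.

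The mitochondrial gene mt-Atp6 stood at 4967 CPM in Sox9HKO replicate 10 and at 661 to 847 in the other 5 libraries, while its neighbour mt-Atp8 stood at 1362 there and 973 to 1356 elsewhere. Across 12808 genes the log2 fold change correlated with GC content (Spearman rho = -0.255) and transcript length (0.294), genes not being independent replicates. Median log2 fold changes ran from -0.18 in the shortest decile of genes to 0.20 in the longest.

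Sox9 was higher in the libraries labelled Sox9HKO. A trend on gene length and GC as the whole cause was argued against, since Sox9 stood at 1.69 with the trend removed. More ductular cells as the whole cause was argued against in both forms tried, the second added after the first had been seen. Sox9 less the ductular marker mean differed by 0.89 ± 0.26 (SE), higher in 3 of 3 libraries, and 7 of 13 markers lay below Sox9 by more than 2 combined SE, exactly the number set as the bound, while the other 6 did not, Spp1 (1.45) and Epcam (1.28) among them. Exchanged labels, or a transcript that persists after exons are deleted, cannot be told apart from a true rise. Whole-gene counts (log2 fold change 1.73) hold no exon-level reads. Nor do they separate cell types, so a loss limited to some cells, hidden by Sox9 of other cells, also stays open. An effect of the genotype itself stays open too.

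At the preset correlation camera put the matrix, ductular and macrophage lists higher and the hepatocyte list lower in the libraries labelled Sox9HKO. With the length and GC trend removed 3 of the 4 lists stayed past the camera threshold. The 3 higher lists did so, 3 of 3, which argues against the trend as their whole cause. The hepatocyte call ended as its median moved from -0.23 to -0.16, so its share in the trend cannot be told apart. A lower hepatocyte share alone would raise endothelial markers as well, if their level per cell stayed the same. The matrix mean less the endothelial mean differed by 0.75 ± 0.15 (SE). On that condition this argues against a lower share as the whole cause of the higher matrix list, and of that list only. Ductular, macrophage and neutrophil lists were also higher, and the contrast does not show how far a lower share raised those. A change in matrix-producing cells, or the genotype, stays possible.

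At the preset correlation camera put the lipogenesis, cholesterol and stress response lists lower in the libraries labelled Sox9HKO. All 3 of 3 stayed past the camera threshold with the length and GC trend removed, which argues against that trend. Feeding state at collection could not be decided, since 7 fasting-induced genes had a median of -0.0071 and went both ways. Irs2 (1.52 ± 0.43, SE), Igfbp1 (0.92 ± 0.63) and Txnip (0.23 ± 0.41) were positive. Bcl6 (-0.43 ± 0.44), Angptl4 (-0.19 ± 0.31), Klf15 (-0.12 ± 0.27) and Cebpb (-0.0071 ± 0.19) were negative. Time of day also stays open, as the clock contrast differed by 0.12 ± 0.57 (SE), and so does the genotype, which was not tested apart from these.

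The 6 libraries allow 10 splits into 3 against 3, too few for a share under 0.05. The labelled split gave 0 genes in edgeR, and the highest other gave 4; 10 of 10 splits had at least 0. It gave 2800 genes at an unadjusted p under 0.05 (1 split as high, the labelled one itself, highest other 1465). In DESeq2 it gave 605 (1 split as high, again itself, highest other 230). It gave 11 lists in camera, a number that 4 splits reached, the labelled one among them (highest other 12). Other groupings of these libraries thus also moved lists together. Among the 11 called lists the labelled split had the lowest camera p of the 10 for the stress response (3.25e-06, lowest other 2.51e-04), lipogenesis (0.00209, lowest other 0.0118) and matrix (9.69e-10, lowest other 1.87e-09). For the other 8 another split gave a lower p. That p was 1.15e-14 against 5.73e-04 for cell cycle, 2.71e-10 against 1.77e-06 for ductular markers, 4.25e-09 against 0.00107 for macrophages and 4.91e-07 against 0.0118 for lymphocytes. It was 9.88e-11 against 0.00437 for fatty acid oxidation, 1.76e-08 against 8.24e-04 for cholesterol, 1.29e-04 against 1.90e-04 for neutrophils and 0.00892 against 0.0107 for hepatocyte genes.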
